A study of Mus musculus with 4 samples.

How the data were processed

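Total RNA of 4 libraries, 2 with a control hairpin and 2 with a hairpin against Lncenc1, was depleted of ribosomal RNA and sequenced as strand-specific libraries, per the labels' protocols. The submitters' processing notes name TopHat2, HTSeq, DESeq2 1.8.2 and the genome build mm9, without giving their order or settings. The annotation release and the strand setting of the counting are not given in the sources used here.

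The 1 deposited table holds a row per gene and no column per library. Per the file headers, it gives the mean normalized read count, a signal that is never negative, which the authors computed over all 4 libraries after division by size factors. The log2 fold change and its standard error, also log2, were computed by the authors. The deposited Wald statistic, a score, equals the fold change divided by its error for every gene, as checked on the values. The p-value and the adjusted p-value are the authors' own, and 14070 of 19840 genes have an adjusted one, all with a mean of at least 8.36. The numerator of the fold change is not given in the sources used here, and groups are named by their Lncenc1 level, as the report states. Gene names were matched by Ensembl identifier without version, and 19707 of 19840 matched. The annotation used here is of another build than the authors' and gave names and transcript sequences, and no coordinates.

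The edgeR test fixed for counts per library was not run, since the table holds another unit and no value per library, so the authors' own fold change, standard error and adjusted p under 0.05 are the main result, the fallback fixed before the data were examined. The groups have 2 libraries each, and no replicate number could be used. DESeq2 was not run here.

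Read counts per library were recovered from the deposited means, a step chosen after seeing the data. A deposited mean is a sum of 4 whole counts, each times a fixed step. The steps were read from the values that recur among low genes, and the fold change told which of 2 groups each step belongs to. All whole-number combinations that give a mean to 15 significant digits were listed, and where several did, the one whose refitted fold change lay within 0.00001 of the deposited one was taken, if the next was at least 10 times worse. A single solution was taken if its refitted fold change lay within 0.001 or if a library had under 1 expected read, where the deposited fold change is no check. This gave counts for 19825 of 19840 genes (99.9%). The other 15 are abundant, with means of at least 33504, and hold 11.5% of the summed mean normalized counts. Of 14050 tested genes with reads in both groups, 13909 gave the deposited log2 fold change within 0.00001. The size factors are 1.95 for H1, 0.797 for H2, 0.811 for L1 and 0.809 for L2. Genes with few reads are included, and the smallest total over the 4 libraries is 2 reads. On a simulated table of 18186 genes 18181 were accepted, and all 18181 had the right counts. Size factors that were multiples of one another would leave several solutions. Intervals and floors from counts cover counting error only, and 3 reads are 1.54 normalized reads in H1 and 3.76, 3.70 and 3.71 in H2, L1 and L2.

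The recovered counts entered only descriptions per library and alternatives: a negative binomial Wald refit at the dispersion that each deposited standard error implies, on 14050 genes, and limma voom. The refit gave the fits without 1 library each, in which the lone library of a group is assumed to vary like the others, and the fit with library totals. The fits without 1 library kept the dispersions implied by all 4 libraries. A call lost in them can thus also come from those dispersions or from fewer libraries. In simulated data of 14070 genes with 200 changed, that Wald test called 12%, 50%, 60% and 74% of genes changed 1.5-, 2-, 3- and 4-fold, and 6 unchanged genes. Without 1 library it called 6%, 28%, 48% and 64%, and 1 unchanged gene. Voom called 6%, 36%, 54% and 68%, and 18 unchanged genes. The simulated Wald test was given the dispersions from which the counts were drawn, the same in both groups, while voom estimated its variances. The simulation therefore cannot show which of these tests is more reliable on the data.

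The 24 gene lists, fixed before the data were examined, were glycolytic enzymes; glucose and lactate transport and glycolytic regulators; hypoxia and HIF targets; TCA cycle; nuclear-encoded oxidative phosphorylation; mitochondrially encoded genes; naive pluripotency; core pluripotency; primed epiblast; mesendoderm; primitive endoderm; neuroectoderm; trophoblast; 2-cell-like; fibroblast markers; interferon response; p53 targets; integrated stress response; immediate early genes; cholesterol synthesis; cell cycle; replication-dependent histones; imprinted genes; and RNA-binding proteins around Ptbp1 and Hnrnpk. Each was tested with cameraPR on the deposited Wald statistic at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 24. Camera with an estimated correlation and fry were run on log2 normalized counts with 2 added. With an estimated correlation camera uses the few residual degrees of freedom of the 4 libraries, unlike at the preset correlation. On simulated data 1% of 200 random lists had a cameraPR p under 0.05, and a list of 20 genes changed 1.5-fold had p = 5.45e-12, against 0.0603 by camera with an estimated correlation (0% of the random lists) and 0.0365 by fry (3%). The simulated genes were drawn independently of one another. These shares therefore cannot show how often the tests call lists whose genes are correlated. The median, mean and test differed in sign for 5 lists (transport and regulators, HIF targets, primed epiblast, immediate early genes, RNA-binding proteins).

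Genes named were Lncenc1, all glycolytic enzymes, of each other list the called members with the largest difference (at most 4) or, with none called, at most the 2 with the smallest p, and the 10 called genes with the largest difference in each direction among those with a mean of at least 50 normalized reads whose groups did not overlap, leaving out predicted gene models, clones and pseudogenes. Psat1, Atf4, Ddit3, Mdm2, Cdkn1a, Nanog, Pou5f1, Sox2, Cdx2, Ptbp1, Hnrnpk, Pgk1-rs7, P4ha1, P4ha2, Mxi1, Syce1, Hprt, Aprt and the genes called by voom were named after their values were seen. Library similarity used log2 normalized counts plus 1 of genes with that mean. Alternatives were adjusted p limits of 0.01 and 0.1, a 2-fold minimum, a mean of at least 50, no filter, library totals, another glycolysis list and each library left out. Computing used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.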

Results

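RNA was sequenced from naive mouse embryonic stem cells, pluripotent cells kept in their ground state with 2i/LIF, a medium of kinase inhibitors and leukaemia inhibitory factor. Cells were infected with a lentivirus coding for a control hairpin (shCtrl) or for a hairpin against the long noncoding RNA Lncenc1 (shLincenc1 in the labels) and were selected with puromycin for 2 days. Each group held 2 libraries of total RNA depleted of ribosomal RNA. The labels do not say that the libraries of a group came from separate cultures, so the p-values rest on a spread between libraries that may be technical. They use a dispersion per gene common to both groups, and so do not measure the spread within either group. The growth protocol names 2 cell lines, E14TG2a and R1, and the labels do not tie a library to either. Per the protocols 2 hairpins were designed per gene, and the labels do not say which of them a library carried. The libraries of a group may thus differ in hairpin. The deposited table gives 1 comparison of the 2 groups, with a fold change, its standard error and p-values for 19840 genes, and does not state which group was the numerator. The numerator group had the higher Lncenc1 level and is called the Lncenc1-high group below, and the other is called the Lncenc1-low group. If the hairpin lowered its target, the Lncenc1-low group is the shLincenc1 group, and the table cannot then serve as a check of the knockdown itself. Whole read counts of the 4 libraries were recovered from the deposited means for 19825 genes. They summed to 26839434 reads in the deeper library of the Lncenc1-high group (H1), 11120881 in the other (H2), 11338852 in the deeper library of the Lncenc1-low group (L1) and 10698451 in the other (L2).

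Lncenc1 was 3.21-fold higher in the Lncenc1-high group by the authors' deposited table, with no overlap of the libraries. Its normalized read count was 6400 in H1 and 7250 in H2, against 2126 in L1 and 2121 in L2. The authors' deposited table gives Lncenc1 (ENSMUSG00000078952.8) a log2 fold change of 1.68 ± 0.19 (SE) between the Lncenc1-high and the Lncenc1-low group, with a DESeq2 adjusted p of 2.67e-16. The low libraries kept a measurable level of the transcript, at a mean of 2123 ± 3.55 normalized reads (SD, n = 2) against 6825 ± 601 (SD, n = 2).

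The comparison addresses what changes in naive stem cells with the level of Lncenc1, and the title of the series names glycolysis. At a DESeq2 adjusted p under 0.05 the authors' deposited table holds 215 changed genes among 14070 tested, 71 of them higher in the Lncenc1-high group and 144 higher in the Lncenc1-low group. Of these, 163 differed at least 2-fold, 41 in the first direction and 122 in the second. In all 215 genes both libraries of one group lay above both of the other, which held for 41.3% of all tested genes and for 33.3% of them by chance. The count depended on the test and on single libraries. Limma voom on the recovered counts called 8 genes, namely Lncenc1, Serpine2, Slc39a14, Fstl1, Rtkn and the gene models Gm10800, Gm11168 and Gm26870. A negative binomial refit called 49 genes without L2, 56 without H1, 80 without H2 and 196 without L1.

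Among called named genes with a mean of at least 50 normalized reads, the largest difference toward the Lncenc1-high group was that of Chac1, an enzyme that degrades glutathione, with a log2 fold change of 2.73 ± 0.50 (SE) in the authors' deposited table. Next came T (brachyury, the mesoderm transcription factor) at 2.45 ± 0.50 (SE), Vrtn at 2.40 ± 0.64 (SE) and Nupr1, a stress-induced nuclear protein, at 2.14 ± 0.40 (SE), all in the authors' deposited table. Hdac7, a histone deacetylase, Pramef17, Ndufa4l2, a paralog of a respiratory chain subunit, Meis2, a homeobox factor, Maml2, a coactivator of Notch signalling, and Susd1 followed, with log2 fold changes from 2.08 down to 1.88 in the authors' deposited table. In the refit 4 of these 10 genes stayed called without H1, 4 without H2, 6 without L1 and 4 without L2.

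Toward the Lncenc1-low group the differences were larger. Perp, a desmosomal membrane protein and p53 target, had 18.96 ± 7.30 normalized reads (SD, n = 2) in the Lncenc1-high group and 463 ± 431 (SD, n = 2) in the Lncenc1-low group. The authors' deposited table gives Perp a log2 fold change of -4.60 ± 1.10 (SE). Xkrx followed at -3.82 ± 1.12 (SE), Cyp1a1, a cytochrome induced through the aryl hydrocarbon receptor, at -3.76 ± 0.72 (SE) and Rhox6, an X-linked homeobox gene of placenta and germ cells, at -3.51 ± 0.68 (SE) in the authors' deposited table. Parm1, Fcgr2b, the inhibitory receptor for immunoglobulin G, Dsc2, a desmosomal cadherin, Mettl21e, Serpine2, an inhibitor of serine proteases, and Mxd4, a MYC antagonist, had log2 fold changes from -3.35 to -3.00 in the authors' deposited table. Serpine2 was the most even of these, with 54.4 and 46.4 normalized reads in H1 and H2 against 407 and 430 in L1 and L2. Dsc2 rested on 1 library, with 220 normalized reads in L2, 18.5 in L1 and 17.97 in H1. In the refit 4 of these 10 genes stayed called without H1, 8 without H2, 7 without L1 and 4 without L2.

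**Figure D1:**
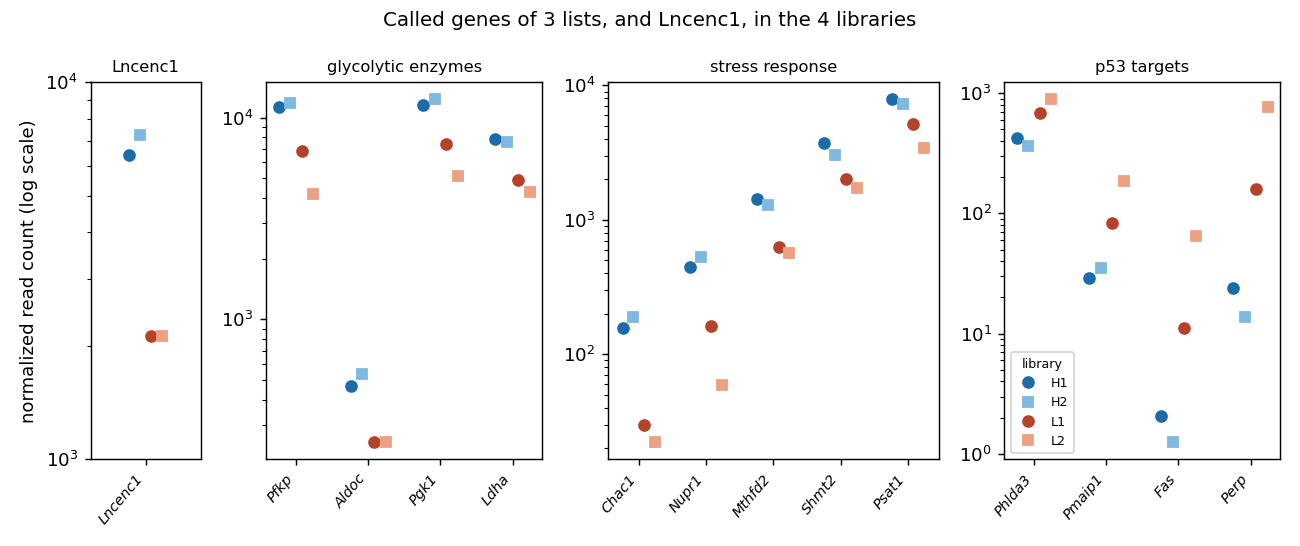
Normalized read counts (log scale) of Lncenc1 and of the called members of 3 gene lists in the 4 libraries, 1 point per library, blue for the Lncenc1-high group and red for the Lncenc1-low group. Lncenc1 lies at 6400 and 7250 in H1 and H2 and at 2126 and 2121 in L1 and L2, and in the p53 targets L2 lies above L1.

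Glycolytic enzymes were higher in the Lncenc1-high group. Of 18 enzymes tested, 4 were called, each higher in that group, and 14 did not pass, with a cameraPR adjusted p of 1.53e-08 for the list. With an estimated correlation between genes the camera p was 0.0817 (adjusted p = 0.811). Pfkp, the platelet form of phosphofructokinase, had 11519 ± 354 normalized reads (SD, n = 2) in the Lncenc1-high group and 5491 ± 1882 (SD, n = 2) in the Lncenc1-low group. The log2 fold changes in the authors' deposited table were 1.07 ± 0.23 (SE) for Pfkp, 1.02 ± 0.28 (SE) for Aldoc, a form of aldolase, 0.93 ± 0.21 (SE) for Pgk1, phosphoglycerate kinase, and 0.75 ± 0.18 (SE) for Ldha, lactate dehydrogenase A, with DESeq2 adjusted p from 0.00117 to 0.026. Adjusted over the list alone, 6 enzymes passed, the same 4 with Tpi1 (0.57 ± 0.19, SE) and Pfkl (0.54 ± 0.19, SE), again from the authors' deposited table. The other members were Gpi1, Aldoa, Pkm, Pfkm, Gapdh, Eno2, Eno1, Pgam1, Ldhb and Hk2, at log2 fold changes from 0.09 to 0.51 in the authors' deposited table, and Hk1 and Eno3 at -0.26 and -0.08. The median over the list was 0.36. In 12 of the 18 both high libraries lay above both low libraries, and in 0 the reverse. Voom called 0 of the enzymes. Of the 4 called, the refit kept 2 without H1, 1 without H2, 3 without L1 and 0 without L2, where the list had a cameraPR p of 4.62e-06.

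Pgk1-rs7, an intronless copy of Pgk1 chosen after its values were seen, was also called, with 0.87 ± 0.24 (SE) in the authors' deposited table, and reads can be split between the pair. It was not called in the refit without L2 (adjusted p = 0.63).

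Of 16 glucose and lactate transporters and glycolytic regulators 1 was called, the lactate exporter Slc16a3, at a log2 fold change of 1.31 ± 0.29 (SE) in the authors' deposited table (list adjusted p = 0.303). Slc16a3 was not called without H1 (0.90, adjusted p = 0.492) or without L1 (1.18, adjusted p = 0.0669). The 18 tested hypoxia-inducible factor targets held 1 gene higher in each group, the growth factor Vegfa at 1.54 ± 0.36 (SE) and Ddit4, an inhibitor of mTOR signalling, at -1.21 ± 0.35 (SE) in the authors' deposited table (list adjusted p = 0.668). Without L2 neither was called (Vegfa adjusted p = 0.49, Ddit4 adjusted p = 1), nor without H1, and without H2 Vegfa alone was. Of 31 nuclear-encoded genes of oxidative phosphorylation 1 was called, Cox5a, a cytochrome oxidase subunit, at -0.97 ± 0.27 (SE) in the authors' deposited table (list adjusted p = 0.40), and it was lost without any 1 of H1, H2, L1 and L2 (adjusted p from 0.0634 to 0.549). Of 20 genes of the tricarboxylic acid cycle DESeq2 in the authors' deposited table and voom each called 0, with 0 at an unadjusted p under 0.05 (list adjusted p = 0.246). The smallest p was that of Cs, citrate synthase, at 0.44 ± 0.29 (SE) in the authors' deposited table. Of 13 mitochondrially encoded genes DESeq2 in the authors' deposited table called 0, and voom called 0 of the 11 with recovered counts. At an unadjusted p under 0.05 were 2, mt-Atp8 at 0.60 ± 0.24 (SE) and mt-Nd6 at -0.58 ± 0.27 (SE) in the authors' deposited table (list adjusted p = 0.0599). The mitochondrial list passed, higher in the Lncenc1-high group, without H2 (adjusted p = 0.0221), without L1 (adjusted p = 0.00156), by ranks (adjusted p = 0.0113) and with no filter (adjusted p = 0.0192), and not without L2 (adjusted p = 0.985) or H1 (adjusted p = 0.236). Its camera p with an estimated correlation was 0.494. That camera test and the fits without 1 library covered the 11 genes with recovered counts, while ranks and no filter covered all 13.

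Genes of the integrated stress and unfolded protein response were higher in the Lncenc1-high group. Of 20 tested, 5 were called, all in that direction, and 8 passed when adjusted over the list alone, with a cameraPR adjusted p of 1.40e-10 for the list. With an estimated correlation the camera p was 0.0395 (adjusted p = 0.811). Besides Chac1 and Nupr1 the called genes were Mthfd2 and Shmt2, enzymes of mitochondrial one-carbon metabolism, at 1.18 ± 0.22 (SE) and 0.86 ± 0.21 (SE), and Psat1, of serine synthesis, at 0.83 ± 0.22 (SE) in the authors' deposited table. Atf4, the central transcription factor of the response, had a log2 fold change of 0.44 ± 0.23 (SE) and Ddit3 one of -0.45 ± 0.52 (SE) in the authors' deposited table, and neither passed. Of the 5, the refit kept 3 without H1, 4 without H2, 5 without L1 and 2, Chac1 and Mthfd2, without L2.

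Targets of p53 were higher in the Lncenc1-low group. Of 20 tested, 4 were called, all in that direction, and 9 passed when adjusted over the list alone, with a cameraPR adjusted p of 6.71e-09 for the list. With an estimated correlation the camera p was 0.141 (adjusted p = 0.828). With Perp the called genes were the death receptor Fas (-4.44 ± 1.27, SE), the BH3-only protein gene Pmaip1 (-2.08 ± 0.56, SE) and Phlda3 (-0.99 ± 0.26, SE), by the authors' deposited table. Fas rested on 4 and 1 reads in H1 and H2 and on 9 and 52 in L1 and L2. Mdm2, the ubiquitin ligase of p53, had -0.68 ± 0.21 (SE) and the cell cycle inhibitor Cdkn1a -0.29 ± 0.29 (SE) in the authors' deposited table, and neither passed over all genes. Of the 4, the refit kept 4 without L1 and 0 without H1, H2 or L2, and without L2 the list had a cameraPR p of 0.000258.

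Pluripotency genes held no called member. Of 20 naive pluripotency genes DESeq2 in the authors' deposited table and voom each called 0, with 5 at an unadjusted p under 0.05 (list adjusted p = 0.0794). The naive list passed, higher in the Lncenc1-high group, without H2 (adjusted p = 0.0173), without L1 (adjusted p = 0.00667), by ranks (adjusted p = 0.0335) and with no filter (adjusted p = 0.0321), and not without L2 (adjusted p = 0.78) or H1 (adjusted p = 0.318). Its camera p with an estimated correlation was 0.479. The 5 genes included Tcl1 at a log2 fold change of 0.68 ± 0.26 (SE), Fbxo15 at -0.51 ± 0.19 (SE) and the transcription factor Nanog at 0.41 ± 0.20 (SE) in the authors' deposited table. Of 15 core pluripotency genes both called 0, with 1 at an unadjusted p under 0.05, Dppa5a at 0.37 ± 0.17 (SE) in the authors' deposited table (list adjusted p = 0.488). The authors' deposited table gives the transcription factors Pou5f1 0.18 ± 0.18 (SE) and Sox2 0.30 ± 0.20 (SE). Of 16 primed epiblast genes both called 0, with 2 at an unadjusted p under 0.05, the DNA methyltransferase Dnmt3b at -0.72 ± 0.27 (SE) and Sall2 at 1.00 ± 0.45 (SE) in the authors' deposited table (list adjusted p = 0.668).

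The 15 tested genes of the 2-cell-like state, a rare state resembling the early embryo, all had negative fold changes, with a median of -0.53 in the authors' deposited table and a cameraPR adjusted p of 0.000781. With an estimated correlation the camera p was 0.406. DESeq2 in the authors' deposited table and voom each called 0 of them, with 2 at an unadjusted p under 0.05, Tdpoz4 at -2.10 ± 0.63 (SE) and Sp110 at -1.50 ± 0.46 (SE), and these 2 passed when adjusted over the list alone. The list did not pass without L1 (adjusted p = 0.959) or without H2 (adjusted p = 0.0578).

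Lineage lists held single calls. Of 4 mesendoderm genes tested T was the 1 called (list adjusted p = 0.264), and of 10 trophoblast genes Rhox6 (list adjusted p = 0.132). T was not called without H2 (adjusted p = 0.38) or L2 (adjusted p = 0.122), and Rhox6 was not called without H1 (adjusted p = 0.0788). The trophoblast list passed without L1 (adjusted p = 0.0498) and by fry for a change in either direction (adjusted p = 0.00247), with a camera p of 0.51 with an estimated correlation. The trophoblast factor Cdx2 had a log2 fold change of 2.51 ± 0.90 (SE) in the authors' deposited table and did not pass. DESeq2 in the authors' deposited table and voom each called 0 of 10 primitive endoderm genes (list adjusted p = 0.563) and 0 of 7 neuroectoderm genes (list adjusted p = 0.434), with 0 in either list at an unadjusted p under 0.05. The smallest p were those of the basement membrane gene Col4a1 at -1.06 ± 0.55 (SE) and of Nes, coding for nestin, at -0.41 ± 0.27 (SE) in the authors' deposited table. Of 5 fibroblast markers, which feeder cells would bring, both called 0, with 1 at an unadjusted p under 0.05, Fbn1, a microfibril protein gene, at -0.99 ± 0.41 (SE) in the authors' deposited table (list adjusted p = 0.0599). All 5 had negative fold changes in the authors' deposited table, and the list passed by ranks (adjusted p = 0.0284), with no filter (adjusted p = 0.0499) and by camera at the preset correlation on log2 counts (adjusted p = 0.0216). The camera p with an estimated correlation was 0.101.

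Of 18 imprinted genes 1 was called, Peg10, a placental gene derived from a retrotransposon, at -2.43 ± 0.43 (SE) in the authors' deposited table (list adjusted p = 0.083). The imprinted list passed without H2 (adjusted p = 0.0174), without L1 (adjusted p = 0.0498) and by fry for a change in either direction (adjusted p = 0.00772), with a camera p of 0.173 with an estimated correlation. Without H2 the cell cycle genes (adjusted p = 0.0173), immediate early genes (adjusted p = 0.02) and histone genes (adjusted p = 0.000771) passed, and without L1 the cell cycle genes (adjusted p = 0.00874) and cholesterol synthesis genes (adjusted p = 0.0498). With no filter the cell cycle genes also passed (adjusted p = 0.0321). The camera p with an estimated correlation was 0.607 for the cell cycle, 0.794 for the immediate early, 0.713 for the histone and 0.569 for the cholesterol synthesis genes. DESeq2 in the authors' deposited table and voom each called 0 members of 6 more lists. Of 14 interferon response genes 1 had an unadjusted p under 0.05, Oas1a at -1.02 ± 0.31 (SE) in the authors' deposited table (list adjusted p = 0.40). Of 11 immediate early genes 2 did, Jun at -1.50 ± 0.63 (SE) and Etv4 at 0.74 ± 0.32 (SE) in the authors' deposited table (list adjusted p = 0.355). Of 20 cholesterol synthesis genes 2 did, among them Mvk, mevalonate kinase, at -0.51 ± 0.26 (SE) in the authors' deposited table (list adjusted p = 0.282). Of 27 cell cycle genes 3 did, among them topoisomerase Top2a at 0.54 ± 0.19 (SE) in the authors' deposited table (list adjusted p = 0.0794). Of 19 replication-dependent histone genes 1 did, Hist1h2bc at -0.59 ± 0.30 (SE) in the authors' deposited table (list adjusted p = 0.355). Of 9 RNA-binding proteins around Ptbp1 and Hnrnpk 1 did, Ptbp3 at 0.59 ± 0.26 (SE) in the authors' deposited table (list adjusted p = 0.75). Adjusted over the list alone, the hypoxia-inducible factor targets held 3 genes higher in the Lncenc1-high group and 2 in the Lncenc1-low group, the trophoblast genes 1 and 2, the imprinted genes 0 and 2, and the interferon response genes 0 and 1. The transporters and regulators and the mesendoderm genes each kept 1 and 0, the oxidative phosphorylation genes 0 and 1, and each other list without a call had 0 apart from the 2-cell-like genes. Ptbp1, a splicing regulator, and Hnrnpk had log2 fold changes of -0.05 ± 0.18 (SE) and -0.06 ± 0.17 (SE) in the authors' deposited table.

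**Figure D2:**
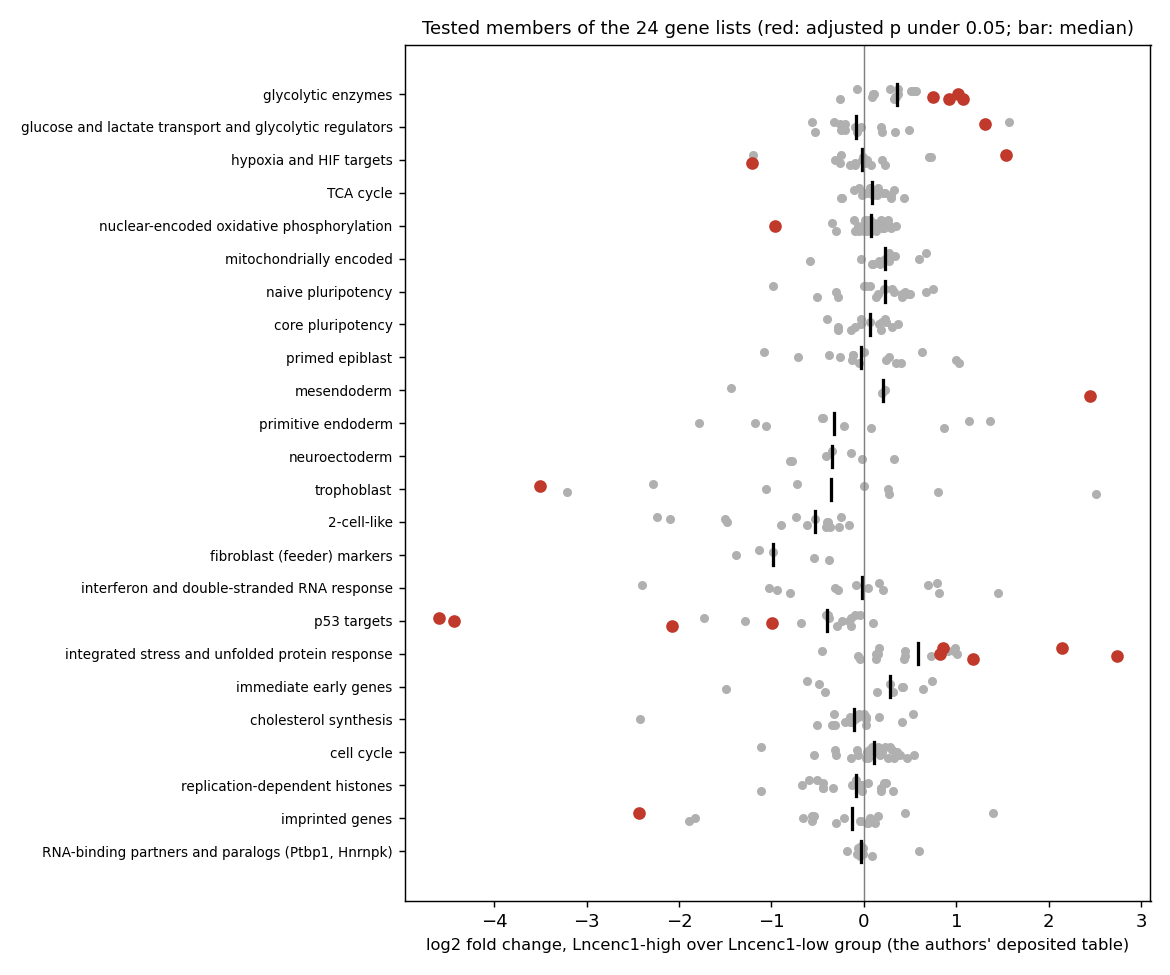
Log2 fold changes (Lncenc1-high over Lncenc1-low group, the authors' deposited table) of the tested members of 24 gene lists, 1 point per gene, red at an adjusted p under 0.05, with a black bar at each list's median. The bar lies at 0.36 for the glycolytic enzymes and at -0.40 for the p53 targets.

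Larger differences lay among genes outside the rule for naming. The authors' deposited table has 17 called genes with a log2 fold change under -5, of which 12 are predicted gene models, at -8.34 to -5.02, and 5 are Nipal4, Gbp2, S100a6, Ptprt and Cpz, all singled out after their values were seen. Nipal4, Gbp2 and S100a6 had 0 reads in H1 and H2, and 16 and 39, 1 and 37, and 10 and 24 reads in L1 and L2. Gm26870 had 1250 and 1469 normalized reads in H1 and H2 and 50627 and 37675 in L1 and L2. Gm10720 had 0 reads in both high libraries, where 3 reads would be 1.54 normalized reads in H1 and 3.76 in H2. Of the 12 models, 11 share at least 40% of their 25-base words with another of them, and in 10 the transcript matches itself best at a shift within 3 bases of 234, so that reads of the shared part cannot be assigned to 1 model.

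**Figure D3:**
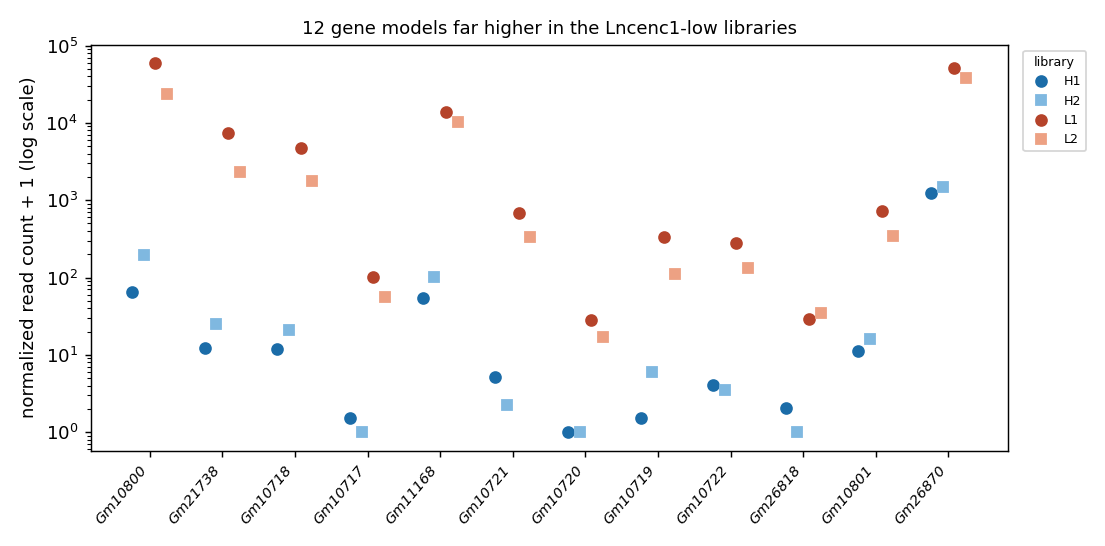
Normalized read counts plus 1 (log scale) of 12 predicted gene models in the 4 libraries, 1 point per library, blue for the Lncenc1-high group and red for the Lncenc1-low group. Each model is higher in L1 and L2 than in H1 and H2, as for Gm26870 with 50627 and 37675 against 1250 and 1469.

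The libraries of the Lncenc1-high group resembled each other more than those of the Lncenc1-low group, and L1 resembled both high libraries more than it resembled L2. Over 11018 genes the Pearson correlation of log2 normalized counts, across genes, was 0.985 between H1 and H2 and 0.947 between L1 and L2, while L1 correlated at 0.962 with H1 and 0.96 with H2, and L2 at 0.941 with H1 and 0.943 with H2, the lowest of the 6 pairs. The difference between the libraries had an SD of 0.33 (log2) in the Lncenc1-high group and 0.62 in the Lncenc1-low group.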

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

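The voom, refit, rank, log2 camera and mixed fry fits were chosen after the data were seen. Lncenc1 kept its direction and its call under every alternative run, with log2 fold changes from 1.59 to 1.77 when 1 library was left out and 1.68 by voom. The 215 calls became 102 at an adjusted p under 0.01 (33 higher in the Lncenc1-high group and 69 in the Lncenc1-low group), and the 71 calls of the first direction became 41 with a 2-fold minimum, which also left 2 of 4 glycolytic enzymes. A stricter limit gives fewer genes by construction. Voom called 8 genes (2 and 6), all among the 215, and 0 glycolytic enzymes, and the cause was not tested. Leaving out 1 library gave 49 to 196 calls, 16 to 83 in the first direction and 33 to 113 in the second, and 0 to 3 glycolytic enzymes, with fewer samples in each fit. The lowest counts came without L2, and 46 of its 49 genes were among the 215. Library totals gave 231 genes and moved the median log2 fold change by -0.03. Of 42 called single genes named by the rule, 29 lost their call without L2, 28 without H1, 21 without H2, 13 without L1, 41 by voom, 17 at an adjusted p under 0.01 and 5 with no filter, with 0 reversed. Among uncalled genes and lists, 8 gained a call without L1, 6 without H2, 1 without H1 and 0 without L2.

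The 4 called lists became 8 with no filter, 7 with ranks, 0 with an estimated correlation, 0 with fry and 2 with mixed fry, which asks for a change in either direction (trophoblast and imprinted genes), and 4 to 9 with 1 library left out, and the cause was not tested. With an estimated correlation the adjusted p was 0.811 for the glycolytic enzymes and for the stress response, 0.828 for the p53 targets and 0.831 for the 2-cell-like genes. By fry, which does not compare a list with other genes, the unadjusted p was 0.0108, 0.0202, 0.0986 and 0.463 in that order. The adjusted p was 0.15, 0.15, 0.394 and 0.71 by fry, and 0.0514, 0.0514, 0.17 and 0.644 by mixed fry. With no filter the mitochondrially encoded, naive pluripotency, fibroblast and cell cycle lists were gained, and by ranks the first 3 of these. With 1 library left out it ranged from 3.79e-08 to 3.70e-05, from 1.70e-11 to 2.14e-07, from 1.97e-09 to 0.00155 and from 8.84e-09 to 0.959. The estimated correlation was 0.0172 for the stress response, near the preset 0.01, and -0.191 for the fibroblast markers. Their camera p on the same log2 counts still rose from 2.56e-07 to 0.0395 and from 0.0045 to 0.101. For these lists the values argue against correlated members as the reason for the weaker result. The glycolytic, p53 and 2-cell-like lists had estimates of 0.0731, 0.212 and 0.629. At the preset correlation their camera p on these counts was 5.64e-06, 1.09e-06 and 0.00222. For these 3 lists the part of correlation cannot be told from that of the few degrees of freedom of the test. No paired analysis was possible because the table carries no replicate numbers, so that the library of one group that shares a number with a library of the other is unknown. The differences H1 minus H2 and L1 minus L2 had a correlation of 0.0589 across genes. DESeq2 and edgeR, with their normalizations, were not run on the recovered counts, nor was a replicate block. The pseudocounts added to the normalized counts before the log2 were not varied. Low genes could not be called, since a gene with a mean under 8.36 had no adjusted p, and the effect of depth was not tested.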

Other observations

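The test of sequence shared among gene models was set before its value was known, and the list tests without L2, with an estimated correlation and of the fibroblast markers were planned, though their use against these explanations was not. The other tests here, ranks and both added lists included, were chosen after the results were seen. Of 38 germline and meiosis genes, in a list written after the calls were known, 7 were called higher in the Lncenc1-low group, 0 in the other and 31 did not pass, with a cameraPR p of 1.15e-08 and a camera p of 0.027 with an estimated correlation. Mael, of the piRNA pathway, had a log2 fold change of -1.80 ± 0.38 (SE), Syce1, of the synaptonemal complex, -1.14 ± 0.26 (SE) and Ddx4, a germ cell helicase, -1.25 ± 0.36 (SE) in the authors' deposited table. Aminoacyl-tRNA synthetases and genes of amino acid supply, also listed after the fact, held 7 of 31 called, all higher in the Lncenc1-high group, with a cameraPR p of 5.16e-18 and a camera p of 0.0874 with an estimated correlation. Nars, the asparaginyl-tRNA synthetase, had 0.83 ± 0.18 (SE), the arginine transporter Slc7a1 0.92 ± 0.21 (SE) and Pck2, the mitochondrial phosphoenolpyruvate carboxykinase, 1.35 ± 0.31 (SE) in the authors' deposited table. Of the 7 germline genes 2 stayed called without H1, 0 without H2, 4 without L1 and 0 without L2, and of the 7 amino acid genes 1, 3, 5 and 2. Neither list is independent evidence, since both were written from these calls.

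Hprt, which the E14TG2a line is known to lack, had 6.16, 7.53, 9.86 and 3.71 normalized reads in H1, H2, L1 and L2, from 12, 6, 8 and 3 reads. Aprt, the other purine salvage enzyme, had 772, 804, 1112 and 1058.

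The 12 predicted gene models, of which 10 have a repeat near 234 bases, were far higher in the Lncenc1-low group. A median 70.8% of a model's 25-base words occurs in another of the 12 models, against at most 0.0873% in 100 random sets of genes. The test covered sequence and not reads, and the counting settings are not given. The same repeat reads may have been counted at several models. The 12 models may thus not be 12 separate results (Gm26818 shares 0% and lacks that repeat). A single library does not account for them, since the lower of L1 and L2 was at least 21.7 times the higher of H1 and H2 in every model with reads in the high group. Carried-over genomic DNA cannot be told apart from transcription: olfactory receptor genes, silent in most cells, summed to 617 and 345 normalized reads in L1 and L2 against 506 and 497 in H1 and H2 (0.681 for the lower L over the higher H), but their own reads would hide a small share of DNA, and L1 and L2 had reads in 17968 and 17140 genes against 16574 in H2, of like depth. An effect of the knockdown on satellite transcripts stays open and was not tested.

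The p53 targets were higher in the Lncenc1-low group. L2 alone does not account for the list's call at the preset correlation, since the cameraPR p without L2 was 0.000258, but 0 of the 4 called targets stayed called without it, and with an estimated correlation the list had a camera p of 0.141 with all libraries. A smaller share of stem cells in the low libraries cannot be told apart: the core pluripotency genes had a median log2 fold change of 0.0625 with a bootstrap 95% interval from -0.14 to 0.23, which reaches past the limit of 0.20 set from the p53 median. The bootstrap drew genes of the list and not libraries, so that the interval leaves out the spread between libraries. All 5 fibroblast markers tested were also on the side of the Lncenc1-low group, with a median of -0.99 and a cameraPR p of 0.015 (adjusted p = 0.0599, and 0.0284 by ranks), but a camera p of 0.101 with an estimated correlation. A response to the hairpin or to loss of Lncenc1 stays open and was not tested.

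The glycolytic enzymes and stress-response genes were lower in the Lncenc1-low group at the preset correlation, while the stress list had a camera p of 0.0395 (adjusted p = 0.811) with an estimated one and kept 2 of 5 calls without L2. L2 alone does not account for the call of the glycolytic list at the preset correlation, since its cameraPR p without L2 was 4.62e-06, but 0 of the 4 called enzymes stayed called without it, and with an estimated correlation the list had a camera p of 0.0817 with all libraries. Less oxygen in the Lncenc1-high cultures cannot be told apart: other targets of hypoxia-inducible factors had a median of -0.02 against 0.36 for the enzymes, but went both ways with an SD of 0.63. Vegfa (1.54), P4ha1 (0.73) and Mxi1 (0.70) passed over that list alone in the one direction and Ddit4 (-1.21) and P4ha2 (-1.20) in the other, by the authors' deposited table. An effect of Lncenc1 itself, which the title of the series names for glycolysis, may remain and was not tested apart from the groups.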
